A study of Mus musculus with 4 samples.

How the data were processed

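RNA-seq libraries from Dynabead-purified glomeruli of 2 NPHS2-Cre +/+ and 2 wild-type mice were compared. The deposited values are FPKM (fragments scaled by transcript length and mapped fragments), as the authors named their table and as its value ranges allow, in 1 table of the whole series. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.5.4b, Cufflinks 2.2.1 and Cuffdiff 2.2.1 with the builds GRCm38 and mm10. The annotation, the strandedness of the libraries, the handling of multiply mapped reads and any scaling between libraries are not given in the sources used here. Columns were matched to samples through the sample descriptions.

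The table lists gene symbols without identifiers. Of its 46955 entries, 1065 join several symbols into 1 locus, and such merged entries were kept and named as merged. Symbols were matched to GENCODE M21 (GRCm38) for identifiers and positions, which 12013 of the 12302 tested entries received. A symbol annotated more than once took the position of its longest gene where all its genes overlap. That rule was added after the results were seen, because it gave St6galnac2 a position.

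FPKM totals ranged from 424980 to 463621 per library. FPKM hold no read totals, but values under 0.1 FPKM fall on steps, and the commonest ratio between libraries gave the relative depth, with 19.5% to 21.9% of ratios within 0.02 (log2) of it. No counting intervals were computed. Of 89 nuclear-encoded ribosomal and oxidative phosphorylation genes, 0 were listed at 0 in any library, but a merged entry of mitochondrially encoded genes with mt-Co1, mt-Co2 and mt-Atp6 was listed at 0 in all 4. The 2 other merged mitochondrial entries, with mt-Nd1 and with mt-Cytb, read 4773 to 13649 FPKM. A listed 0 is therefore not read as absent expression.

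Entries with a mean of at least 1 FPKM over the 4 samples were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended variance prior, two-sided, and Benjamini-Hochberg adjustment at 0.05. The total degrees of freedom were 5.6. A count model was not used because the values are not counts. Of 26 gene lists fixed before the data were examined, 24 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The test was run on simulated data with 200 changed entries in each of 5 simulations of the NPHS2-Cre comparison (12302 entries). It recovered 1.47% of entries at a log2 fold change of 1, 71.3% at 2 and 91.3% at 3, and 5.26% of calls were false.

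Named genes follow a rule fixed before the data were examined. It takes, in each direction, up to 12 passing entries with the largest absolute log2 fold change whose groups do not overlap, up to 4 members of each list with the smallest unadjusted p, the podocyte genes Nphs2, Nphs1, Podxl, Synpo and Wt1, and the sex-linked genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty. Fewer than 12 passed in each direction, so all 17 were taken. Genes named outside the rule, which are copies, neighbours, clock genes and B2m, were chosen after their values were seen.

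Transcripts of the passing entries were searched against all GENCODE M21 transcripts with blastn 2.17.0. Positions were tested against 10000 random draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The alternatives fixed in advance were a pseudocount of 0.1, no filter and a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, rescaling to a common sum (TPM), a prior without a trend, a robust prior, a replicate block, and leaving out each library. A fit of protein-coding unmerged entries was added after seeing the data. A fit without 1 library leaves a group with a lone sample, which is assumed to vary like the other group.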

Results

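RNA was measured in kidney glomeruli, the filtering units of the kidney, taken from male mice at 24 weeks of age and purified with magnetic Dynabeads. There were 2 NPHS2-Cre +/+ mice, which carry Cre recombinase under the promoter of the podocyte gene for podocin, and 2 wild-type mice, all with the strain label 29S6. The series design describes separately isolated biological replicates. The comparison asks whether the Cre driver line differs from wild type with no floxed gene named in the labels. The deposited table held 46955 entries with FPKM values, of which 12302 averaged at least 1 FPKM and were tested. Read totals were not given. The spacing of the lowest FPKM values placed relative depth at 1 and 0.63 in NPHS2-Cre replicates 1 and 2, and at 0.807 and 0.687 in wild-type replicates 1 and 2.

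Glomeruli of NPHS2-Cre mice had higher transcript levels of cytoglobin and of a merged entry of RP23-313J14.7 and the sialyltransferase gene St6galnac2, both within 113.8 kb of chromosome 11, and lower levels of the sorting nexin gene Snx31. Cygb, a globin of fibroblast-like cells, averaged 47.6 ± 2.60 FPKM in NPHS2-Cre and 2.60 ± 1.28 FPKM in wild type (SD, n = 2 each). Snx31 averaged 0.0813 ± 0.00466 FPKM against 18.6 ± 0.183 FPKM (SD, n = 2 each). Trim12a, of a family of restriction factors, was listed at 0 in both NPHS2-Cre libraries and at 10.2 and 9.65 FPKM in wild type. A listed 0 need not mean absent expression, since a merged entry of mitochondrial genes that includes mt-Co1 and mt-Atp6 was listed at 0 in all 4 libraries. Podocyte identity genes, including Nphs2 itself, did not pass the test.

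By limma on log2(FPKM + 1), 8 entries were higher and 9 lower at a Benjamini-Hochberg adjusted p under 0.05, with adjusted p between 0.0123 and 0.0489, counting Gm26465 and Trim12a, each listed at 0 in 1 genotype. In all 17 the groups did not overlap. Across the tested entries the groups lay apart with NPHS2-Cre higher in 18.7% and with NPHS2-Cre lower in 21.2%, where chance gives 16.7% in each direction. An unadjusted p under 0.05 was reached by 1057 entries (8.59%). The median log2 fold change over all tested entries was 0.013. Fold changes on the log2(FPKM + 1) scale understate the change of low genes.

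Of the 17 entries, 8 were protein-coding genes listed alone, 5 were pseudogenes and 2 were merged loci. Among the higher ones, Cygb (chromosome 11, 116645595 to 116654313, GRCm38) rose with a log2 fold change of 3.80 (SE 0.29, adjusted p = 0.0284). The merged entry of RP23-313J14.7 and St6galnac2 (St6galnac2 at chromosome 11, 116675303 to 116694868) rose with a log2 fold change of 2.92, from 3.11 ± 0.607 to 29.9 ± 1.62 FPKM (SD, n = 2 each). BC018473, annotated as an antisense transcript (chromosome 11, 116752167 to 116759373), rose from 0.0336 ± 0.0371 to 7.23 ± 0.618 FPKM (SD, n = 2 each); whether the counting used strand is not given, so its reads cannot be told from those of a transcript on the other strand. Ogn, encoding the matrix proteoglycan osteoglycin (chromosome 13, 49608046 to 49624501), rose with a log2 fold change of 2.27. BC064078, a pseudogene on chromosome 6, rose with a log2 fold change of 2.95. The small nuclear RNA Gm26465 was listed at 0 in both wild-type libraries and at 40.8 and 110 FPKM in NPHS2-Cre, and belongs to a family of near-identical copies.

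**Figure D1:**
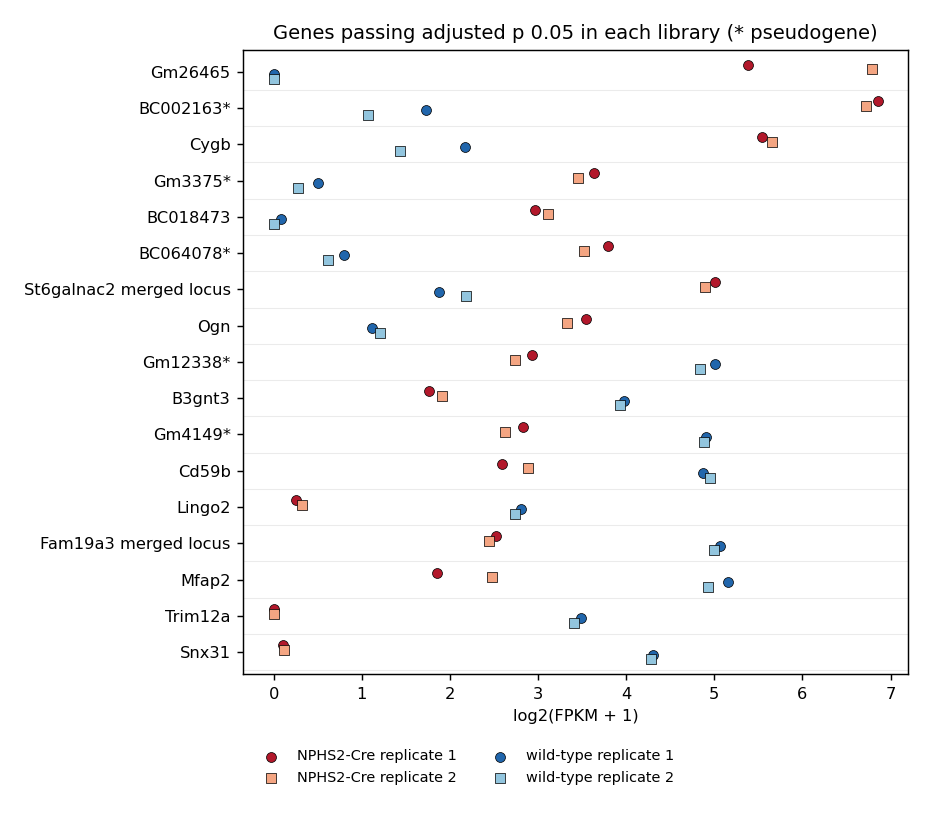
Each point is the log2(FPKM + 1) value of 1 library for the 17 entries that passed, with NPHS2-Cre in red and orange and wild type in blue. The groups do not overlap for any of the 17.

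Among the lower ones, Snx31 (chromosome 15, 36504062 to 36555573) had a log2 fold change of -4.18 (SE 0.21, adjusted p = 0.0123). Mfap2, a component of elastic microfibrils (chromosome 4, 141010418 to 141015984), averaged 3.60 ± 1.38 FPKM in NPHS2-Cre and 32.0 ± 3.55 FPKM in wild type (SD, n = 2 each). Cd59b, which encodes an inhibitor of the complement membrane attack complex (chromosome 2, 104069849 to 104091187), had a log2 fold change of -2.17. The log2 fold changes were -2.49 for Lingo2, a leucine-rich repeat membrane protein gene, and -2.12 for the glycosyltransferase gene B3gnt3. Ogn, Mfap2, Cd59b, Lingo2 and B3gnt3 each had a limma adjusted p of 0.0489, close to the threshold. Among the alternative settings B3gnt3 passed in 3 of 14, Ogn, Mfap2 and Cd59b each in 4 of 14 and Lingo2 in 4 of 13, against 10 of 14 for Snx31. The merged entry of Fam19a3, Gm43584 and Gm6485 had a log2 fold change of -2.55. Its member transcripts have copies of up to 98.4% identity. The most abundant copy, the histone gene H3f3b, averaged 371 FPKM in NPHS2-Cre and 511 FPKM in wild type. H3f3b did not pass and did not offset the change of the merged entry.

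The 3 entries on chromosome 11 spanned 113.8 kb. None of the 18 other tested entries within 500 kb on either side passed, with log2 fold changes from -1.20 to 0.50 and a smallest adjusted p of 0.192. Rnf157 (-1.20), Ubald2 (-0.85), Exoc7 (-0.62) and Mxra7 (-0.56) were lower, each at an unadjusted limma p under 0.05. No other neighbour reached that level in either direction. One of them, the merged entry of 1810032O08Rik, lies between Cygb and St6galnac2 and had a log2 fold change of 0.23. This neighbourhood was singled out after the values were seen.

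**Figure D2:**
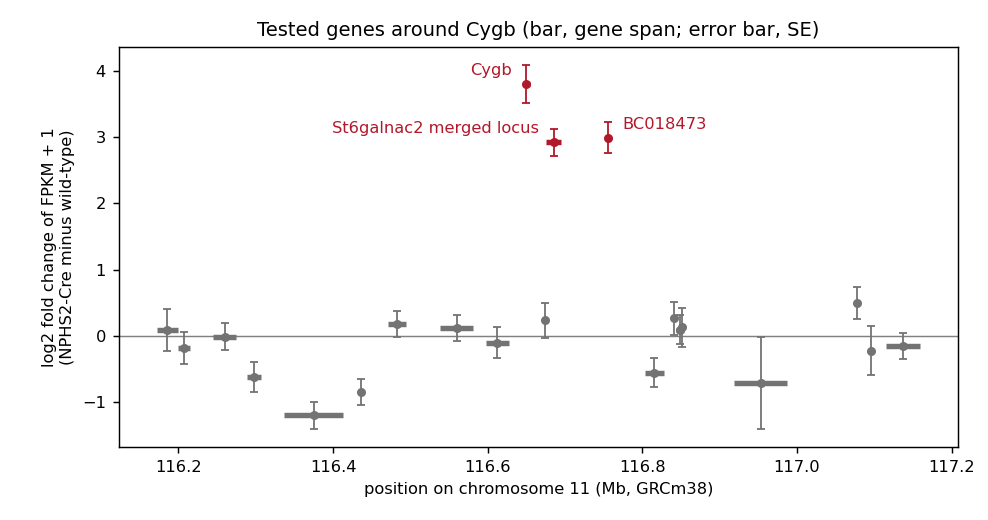
The log2 fold change (NPHS2-Cre minus wild-type, FPKM + 1) of each tested entry is plotted against position on chromosome 11 in GRCm38, with gene spans as bars and standard errors as error bars. Cygb, the merged St6galnac2 entry and BC018473 lie between 2.92 and 3.80, and the other 18 entries lie between -1.20 and 0.50.

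Several of the entries have near-identical copies elsewhere, so their values are uncertain. A copy with at least 90% identity over at least 50% of the transcript was found for 6 of the 17. The pseudogene BC002163 (chromosome 16, 42955631 to 42955949) averaged 109 FPKM in NPHS2-Cre and 1.71 FPKM in wild type, while its parent Ndufs5, a subunit of respiratory complex I, averaged 20.7 and 107 FPKM. The sum of the pair was 130 FPKM in NPHS2-Cre and 108 FPKM in wild type. FPKM are scaled by transcript length, so reads moving between copies of different length need not keep such a sum. Gm3375 and its copy, the merged entry of Mir686 and Psmb5, summed to 37.0 and 37.6 FPKM, although Gm3375 alone had a log2 fold change of 3.16. Gm4149 and Gm12338, with copies Rpl37a and Cox7c, had log2 fold changes of -2.16 and -2.09.

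Without either wild-type library no entry passed, with smallest adjusted p of 0.0612 without replicate 1 and 0.0973 without replicate 2 by limma, and 1021 and 2026 entries at an unadjusted p under 0.05. Without NPHS2-Cre replicate 1 there were 23 higher and 24 lower, without NPHS2-Cre replicate 2 there were 190 and 58, and no entry passed without the filter on low values or after rescaling each library to a common sum.

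Podocyte genes did not pass as a group or singly. The 30 tested members had a median log2 fold change of 0.12 (camera adjusted p = 0.281), and 0 passed over all genes or adjusted over the list alone. The median was 0.20 without NPHS2-Cre replicate 1, -0.010 without NPHS2-Cre replicate 2 and 0.012 without wild-type replicate 2. Nphs2 read 614 and 1723 FPKM in NPHS2-Cre replicates 1 and 2 and 1565 and 720 FPKM in wild-type replicates 1 and 2, a spread within each genotype wider than the difference between them. The log2 fold changes were 0.49 for Nphs1 (nephrin), -0.12 for Podxl (podocalyxin), -0.03 for Synpo (synaptopodin) and -0.27 for Wt1. Leaving out each library gave -0.79 to 0.70 for Nphs2, 0.26 to 0.72 for Nphs1, -0.35 to 0.11 for Podxl, -0.28 to 0.23 for Synpo and -0.50 to -0.034 for Wt1. Cd2ap, an adaptor of the slit diaphragm, had the smallest unadjusted p of the list, with a log2 fold change of 1.27 (SE 0.35) and a limma adjusted p of 0.424, and 0.77 without wild-type replicate 1. Expression of Ddx3y, Kdm5d, Eif2s3y and Uty in all 4 libraries, with the merged Xist entry at no more than 0.0801 FPKM, matched the male label.

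Of 24 lists fixed in advance and tested with camera at a preset correlation of 0.01, 8 passed in the higher direction and 7 in the lower. With an estimated correlation none passed (smallest adjusted p = 0.732 with an estimated correlation), nor did any by the directional fry test (smallest adjusted p = 0.627). The mixed fry test, which asks whether members change in either direction, passed 1 list, smooth muscle and renin (adjusted p = 0.00118). In simulated data with no list changed and a correlation of 0.3 within lists, the preset test called 27.5% of lists. The correlations estimated in the data ran from -0.114 for complement to 0.959 for distal nephron and collecting duct. They were 0.829 for heat shock, 0.334 for glomerular endothelial and 0.171 for kidney injury and inflammation. The simulated rate is therefore not the rate of each list. No member of any list passed over all genes. Adjustment over a list alone, given for single lists, does not correct for the 24 lists tested. The 3 lists that follow passed the preset test in all 4 fits that left out 1 library.

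Heat shock genes, encoding chaperones, were higher, with a median log2 fold change of 1.04 over 13 tested members, all 13 above 0 (camera adjusted p = 5.52e-07, and adjusted p = 0.732 with an estimated correlation). Hspa1b averaged 384 ± 160 FPKM in NPHS2-Cre and 166 ± 10.3 FPKM in wild type (SD, n = 2 each), and Hsph1 had a log2 fold change of 1.94. All 13 were highest in NPHS2-Cre replicate 2, and 0 of the 13 passed adjusted over the list alone. Without NPHS2-Cre replicate 2 the median was 0.66, and the log2 fold changes were 0.71 for Hspa1b and 1.11 for Hsph1.

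Glomerular endothelial genes were lower, with 17 of 19 tested members below 0 and a median log2 fold change of -0.53 (camera adjusted p = 3.96e-06, and adjusted p = 0.732 with an estimated correlation). Kdr, the main VEGF receptor of endothelium, averaged 231 ± 30.1 FPKM against 407 ± 73.9 FPKM, and Sox18, an endothelial transcription factor, had a log2 fold change of -0.95, and of -0.56 without wild-type replicate 1. None of the 19 passed adjusted over the list alone. The proximal tubule list was highest in NPHS2-Cre replicate 1 for 24 of 24 members, and 15 of the 19 endothelial members were lowest in that library; without it the endothelial median was -0.34.

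Kidney injury and inflammation genes were lower, with 11 of 13 tested members below 0 and a median log2 fold change of -0.71 (camera adjusted p = 1.23e-05, and adjusted p = 0.732 with an estimated correlation). The list fixed 20 genes. Havcr1, Lcn2, Spp1, Sox9 and Krt20 were not among those tested, so the result does not cover these injury markers. Adjusted over the list alone, 4 passed: the endothelial adhesion genes Sele and Icam1 (log2 fold changes -2.51 and -1.52), the cytokine gene Tnf (-1.44) and the chemokine gene Ccl5 (-1.06). Sele read 3.25 and 4.94 FPKM in NPHS2-Cre and 17.1 and 44.4 FPKM in wild type. Tnf read 1.15 and 0.823 FPKM in NPHS2-Cre and 3.30 and 5.68 FPKM in wild type. Ccl5 read 0.790 and 0.474 FPKM in NPHS2-Cre and 2.70 and 2.09 FPKM in wild type. Both are low values, on which the added 1 weighs. Markers of glomerular endothelium (17 of 19 below 0, median -0.53) and of immune cells (12 of 15 below 0, median -0.50) were also lower in NPHS2-Cre. The library patterns differed, with 14 of the 19 endothelial members highest in wild-type replicate 1 and 10 of the 15 immune members in wild-type replicate 2. Means relative to all 4 libraries follow for the immune, the endothelial and the injury and inflammation list, in that order. NPHS2-Cre replicate 1 stood at -0.39, -0.40 and -0.46, and NPHS2-Cre replicate 2 at 0.03, -0.11 and -0.39. Wild-type replicate 1 stood at 0.07, 0.42 and 0.10, and wild-type replicate 2 at 0.29, 0.09 and 0.74. The immune list and the injury and inflammation list were thus both highest in wild-type replicate 2. Of the 13 injury and inflammation members, 9 were highest in wild-type replicate 2. The median was -1.11 without wild-type replicate 1, -0.546 without wild-type replicate 2, -0.475 without NPHS2-Cre replicate 1 and -0.917 without NPHS2-Cre replicate 2. Without wild-type replicate 2 the log2 fold changes were -1.85 for Sele, -1.12 for Icam1, -1.12 for Tnf and -1.19 for Ccl5.

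The other lists that passed the preset test lost the call in at least 1 fit without a library, and had adjusted p = 0.732 with an estimated correlation. Higher medians were 0.87 for proximal tubule, 0.92 for distal nephron and collecting duct, 0.63 for parietal epithelium, 0.52 for smooth muscle and renin, 0.37 for the unfolded protein response, 0.28 for nuclear oxidative phosphorylation and 0.18 for ribosomal proteins. Without NPHS2-Cre replicate 1 the median was 0.021 for proximal tubule, -0.49 for distal nephron and 0.13 for oxidative phosphorylation, and it was 0.57 for the unfolded protein response. Without NPHS2-Cre replicate 2 these medians were 1.81, 1.77, 0.44 and 0.11, and that of parietal epithelium was 0.96. Leaving out wild-type replicate 1 gave 0.43 for proximal tubule, 0.13 for distal nephron, 0.47 for oxidative phosphorylation and 0.23 for the unfolded protein response. Leaving out wild-type replicate 2 gave 1.40 for distal nephron, 0.13 for smooth muscle and renin, 0.12 for oxidative phosphorylation and 0.088 for ribosomal proteins. Of the 47 oxidative phosphorylation members, 40 were also highest in NPHS2-Cre replicate 1. Slc5a2, the glucose transporter of the early proximal tubule, read 98.4 and 22.3 FPKM in NPHS2-Cre and 17.1 and 12.5 FPKM in wild type. Ren1, encoding renin, averaged 132 ± 7.91 FPKM against 54.3 ± 12.9 FPKM (SD, n = 2 each), and was the only member of its list to pass adjusted over the list alone. Lower medians were -0.50 for immune, -0.38 for cell cycle, -0.34 for mesangial, -0.28 for extracellular matrix and fibrosis and -0.24 for interferon response. Without wild-type replicate 1 the matrix median turned to 0.027, the mesangial one was -0.15 and the interferon one -0.43. Without NPHS2-Cre replicate 1 the medians were -0.093 for matrix, -0.22 for immune, -0.19 for mesangial and -0.52 for interferon. Without NPHS2-Cre replicate 2 they were -0.49 for matrix, -0.51 for mesangial and -0.036 for interferon, and without wild-type replicate 2 they were -0.57 for mesangial, -0.33 for immune and -0.21 for cell cycle. Col15a1, a basement membrane collagen gene, was the only member of the matrix list to pass adjusted over the list alone, with a log2 fold change of -1.60.

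Median log2 fold changes of the remaining lists were -0.28 for glomerular basement membrane, -0.23 for immediate early, -0.15 for actin and adhesion, 0.14 for hypoxia and glycolysis, 0.07 for p53 and DNA damage, -0.08 for cholesterol synthesis, -0.025 for circadian and -0.014 for complement, and none of these passed in the main fit. Leaving out 1 library turned the sign of each of these medians except that of the immediate early list. The basement membrane, immediate early, circadian and actin lists each gained a call in at least 1 alternative setting. Hspg2, encoding perlecan, was the only member of the basement membrane list to pass adjusted over the list alone, with a log2 fold change of -1.11. The erythroid and mitochondrially encoded lists had too few tested members.

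**Figure D3:**
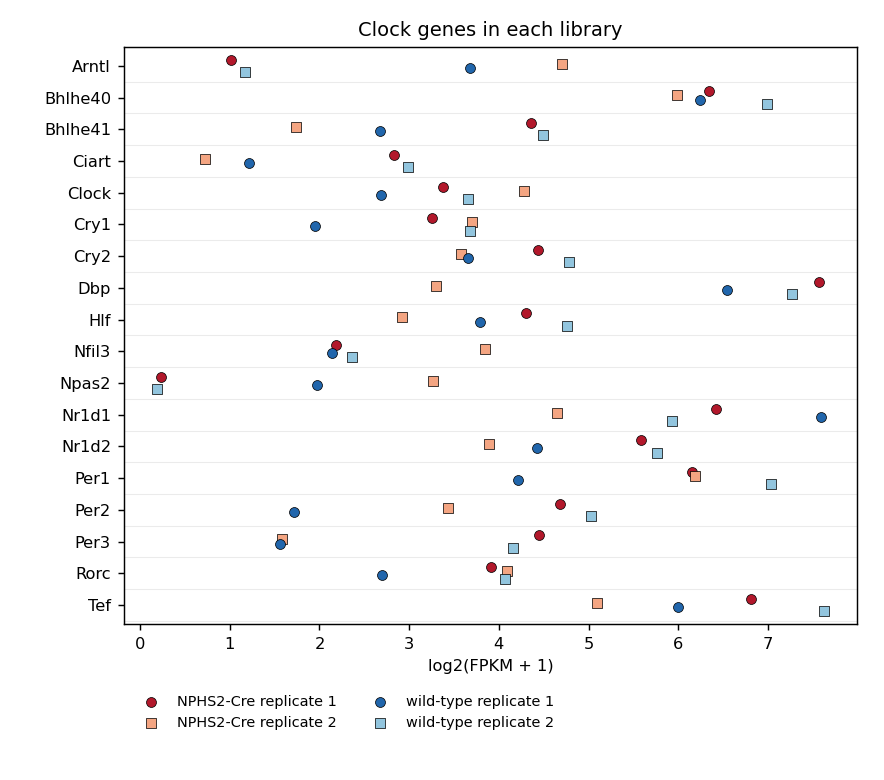
Each point is the log2(FPKM + 1) value of 1 library for the 18 tested clock genes. Dbp ranged from 8.82 to 189 FPKM within NPHS2-Cre, and no clock gene separated the genotypes.

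**Figure D4:**
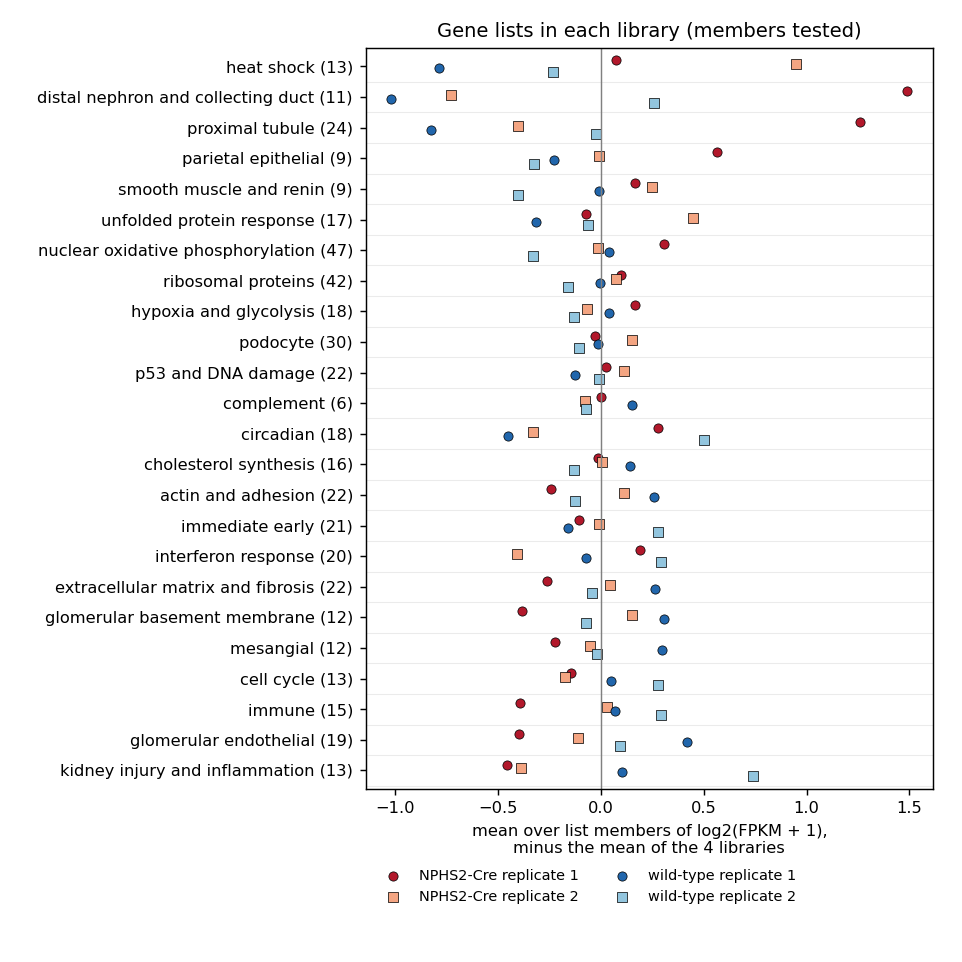
Each point is 1 library's mean over the tested members of a list, in log2(FPKM + 1) relative to the mean of the 4 libraries, with member counts in brackets. The proximal tubule and distal nephron lists stand at 1.26 and 1.49 in NPHS2-Cre replicate 1, and heat shock at 0.95 in NPHS2-Cre replicate 2.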

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

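The fit of protein-coding unmerged entries was chosen after seeing the data. All 17 passing entries kept their direction in each setting in which they were tested. Over the settings the log2 fold change ranged from 3.43 to 4.22 for Cygb, 2.77 to 3.24 for the merged St6galnac2 entry and -2.46 to -2.05 for B3gnt3. It ranged from -2.77 to -2.52 for the merged Fam19a3 entry. Ranges were wider for Snx31 (-6.69 to -4.17), Trim12a (-6.65 to -3.41) and Gm26465 (5.38 to 9.39). Against 8 higher and 9 lower, the lower count was 3 with a pseudocount of 0.1, 3 with median-ratio scaling and 5 without a trend; the higher count was 4 at a mean of at least 5 FPKM. Both were 0 without a filter (smallest adjusted p 0.235, with 1896 at an unadjusted p under 0.05 by limma) and 0 after rescaling to a common sum (0.0511, with 1222). The rescaling raised all values, so 13720 entries were tested instead of 12302 and the added 1 weighed less. The loss can therefore not be put down to the common sum alone, and median-ratio scaling of the 12302 entries kept 10. Protein-coding unmerged entries gave 0 higher and 2 lower. Leaving out each library gave 0 to 190 higher and 0 to 58 lower, and 3 to 5 lists higher; 0 lists passed in either direction with an estimated correlation or by directional fry. The cause was not tested. With a replicate block, 6 were higher and 3 lower, and no list call changed. Same-numbered libraries had an r of deviations of -0.133 and differently numbered ones 0.133. With 2 libraries in each genotype these are 1 value with its sign turned, so they cannot show whether the numbers pair the mice. The labels do not say that same-numbered mice are related.

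Lists reversed in the direction of the test, while the median could keep its sign. Leaving out each library gave medians of -0.485 to 1.77 for distal nephron, -0.477 to 0.159 for glomerular basement membrane, -0.0747 to 0.285 for hypoxia, -0.318 to 0.0695 for actin, -0.517 to -0.0356 for interferon, -0.843 to 0.362 for circadian, -0.373 to -0.0116 for immediate early and -0.200 to 0.040 for cholesterol synthesis, which also reversed without a filter (-0.0728) and by fry (-0.0807). Among genes that did not pass, the ranges were -0.789 to 0.698 for Nphs2, -0.347 to 0.113 for Podxl, -0.284 to 0.227 for Synpo, -0.234 to 0.359 for Kdm5d, -0.969 to 0.222 for Hba-a2, -1.01 to 0.623 for Hba-a1, -0.137 to 1.37 for Hbb-bs, -0.343 to 0.163 for Slc25a37, -0.191 to 1.26 for C3 and -0.0722 to 1.59 for Nfil3. Quantile normalization gave 0.0194 for Nphs2, 0.124 for Synpo and -0.0270 for Kdm5d. Read totals are unknown, so no depth limit was computed.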

Other observations

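Clock genes differed widely between mice of 1 genotype. Dbp, an output gene of the circadian clock, read 189 and 8.82 FPKM in NPHS2-Cre replicates 1 and 2 and 92.2 and 152 FPKM in wild-type replicates 1 and 2. Arntl, encoding the core activator BMAL1, read 1.02 and 25.0 FPKM in NPHS2-Cre and 11.8 and 1.25 FPKM in wild type. Over the 18 clock genes the median absolute log2 difference between libraries of 1 genotype was 1.60, against 0.28 for random lists matched on mean expression, and 0 of 10000 such lists reached it. The random lists were drawn gene by gene, so any list of genes that vary together could exceed them. The distal nephron list also differed within genotypes, with means of 1.49 and -0.73 in NPHS2-Cre and -1.02 and 0.257 in wild type. The draws therefore do not single out the clock genes. Across the 18 genes, which are not independent replicates, the differences between replicates 1 and 2 in the 2 genotypes had a Pearson r of -0.546 (permutation p = 0.0257, adjusted p = 0.0514) and a Spearman rho of -0.393 (permutation p = 0.112, adjusted p = 0.112). Without the 2 genes farthest from the median, Arntl and Npas2, r was -0.066, so the correlation rests on those genes. The r does not carry a shift common to the genes. For Dbp, Tef, Hlf, Per3, Ciart and Bhlhe41 the median log2 difference of replicate 1 minus replicate 2 was 2.36 in NPHS2-Cre and -1.70 in wild type. Those genes were picked from the 18, and others did not turn between the genotypes. Nr1d1 was higher in replicate 1 of both, at 84.5 and 24.1 FPKM in NPHS2-Cre and 192 and 60.0 FPKM in wild type. Clock was lower in replicate 1 of both, at 9.39 and 18.4 FPKM in NPHS2-Cre and 5.42 and 11.6 FPKM in wild type. These relations were computed after the values were seen.

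B2m, the light chain of class I major histocompatibility molecules, read 999 and 1092 FPKM in NPHS2-Cre and 2072 and 2527 FPKM in wild type, and did not pass (limma adjusted p = 0.379). It was noticed after the values were seen.

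Of the tests that follow, only the 10 Mb window was fixed before its result was seen; the others were chosen after. The passing entries lie on 10 chromosomes, with 3 of them within 113.8 kb on chromosome 11. Gm12338 also lies on chromosome 11 (75599763 to 75599954). A single chromosomal segment carried with the transgene from another strain could hold Gm12338 too if wider than 10 Mb. Such a segment is argued against for the others of the 14 entries outside the most crowded 10 Mb window. For the 3 inside it, the window was reached in 6.28% of 10000 random draws, so a segment stays open; before St6galnac2 was given its position, a correction made after the cluster was seen, the most crowded window held 2 entries, no more than the median of draws. An effect of the integrated transgene on its neighbours may account for Cygb, the merged St6galnac2 entry and BC018473, but the 200 kb window reached in 0.01% of draws was sized after the cluster was seen and the integration site is not in the files. A strain background that differs between the groups at many places could also put genes on 10 chromosomes, where random draws gave a median of 11, and the single strain label leaves it untested, for Trim12a and Cd59b among others.

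Processed pseudogenes made up 23.5% of the passing entries and 2.35% of tested entries with a position (Fisher's exact p = 0.000556, two-sided, entries not independent). No copy at 90% identity over 50% of the transcript was found for 11 passing entries, and shorter or less similar stretches were not searched. Among the 6 that have one, the most abundant copy moved the other way by 0.5 to 2 times as much FPKM in 4. That criterion does not allow for differing transcript lengths, by which FPKM are scaled. Random partners gave 0.791 on average and reached 4 in 0.19% of draws, but they were matched on FPKM only, not on gene family. The copies Rpl37a and Cox7c had log2 fold changes of 0.164 and 0.345, near the medians of the ribosomal (0.18) and oxidative phosphorylation (0.28) lists. For Gm4149 and Gm12338 the draws therefore cannot tell shared reads from a shift of the copy's gene family. Reads that move between copies, for instance through strain variants, remain a candidate explanation for the 4 entries, and no biological explanation was tested.

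The higher proximal tubule values came with NPHS2-Cre replicate 1. A change shared by both NPHS2-Cre mice at the size seen in replicate 1 is argued against. In NPHS2-Cre replicate 2 the list differed from the wild-type mean by a median of 0.02 (quartiles -0.29 and 0.30). The wild-type libraries also differed from each other, at -0.826 in replicate 1 and -0.0256 in replicate 2 relative to the mean of all libraries. NPHS2-Cre replicate 2 lay between them at -0.406, so a smaller shared change cannot be judged. The distal list exceeded the other 3 libraries by a median of 2.15 in NPHS2-Cre replicate 1, with 11 of 11 members highest there, and the proximal list by 1.76. Tubule fragments carried over in that library may explain both, as a hypothesis from the same data; Aldob, an abundant tubule gene, read 379 FPKM there and 112 FPKM in NPHS2-Cre replicate 2.

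The 4 libraries allow 3 splits into pairs, too few for a share under 0.05. The real split gave 17 passing entries, reached by 1 split, and the highest of the others gave 0, while those others passed 7 and 10 lists against 15 in the real split.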
